A study of Mus musculus with 21 samples.

How the data were processed

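Expression arrays from 21 mouse heart samples were analysed in 4 groups taken from the sample titles: wild-type sham (n = 4), wild-type TAC (n = 6), G4D sham (n = 5) and G4D TAC (n = 6). The labels give total RNA with a biotin label and name cardiac myocytes as the source. Whether cells were isolated or tissue was used is not stated. Nothing beyond the titles says that replicates are separate animals, and the labels give no batch or date.

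The deposited values are log2 probe-set values, 1 per array, which the authors made with PLIER, a probe-level summary method, per the labels. Its version, the background correction and the normalization are not stated. The log2 scale was inferred from the values, which ran from -13.5 to 15.1, and from the hybridization spike-ins, which rose by 5.21 units from bioB (6.76) to cre (11.97). Array medians ran from 4.31 to 5.33, a range of 1.02.

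The comparisons, the lists, the filter, the naming rule and the first group of alternatives below were set before the data were examined. By a rule for medians that differ, quantile normalization between arrays came first. Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 carried exactly 1 gene symbol, 932 carried several and 9160 none. A probe set was kept when it carried 1 symbol and its mean over the 21 arrays was at or above the 40th percentile (4.35). Each gene was represented by its brightest probe set, which gave 13279 tested genes of 18193 symbols. Symbols came from the platform annotation, and 7 list symbols were updated to match it.

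Group means were fitted in limma 3.58.1 under R 4.3.3 with all 21 arrays in 1 fit and no covariate. Moderated statistics came from eBayes, with 17 residual degrees of freedom (20.7 with the prior). The 5 comparisons were G4D over wild type in sham, TAC over sham in wild type, TAC over sham in G4D, G4D over wild type after TAC, and the interaction, the TAC effect in G4D less that in wild type. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. Every adjusted p of a gene is from limma. Both Gata4 probe sets, and those of Gata6, were also fitted whatever their level in a fit of all probe sets, whose standard errors differ slightly from those of the tested genes.

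In all, 28 gene lists were fixed, 9 of cell type markers and 19 of functions, with 562 members, of which 523 had a probe set, 486 were tested and 39 had no match. The cell type lists were fibroblast, endothelial, smooth muscle and pericyte, macrophage and myeloid, lymphocyte, atrial, erythroid, adipocyte, and epicardial and mesothelial markers. The others were fetal and hypertrophic genes, reported direct Gata4 targets, cardiac transcription factors, sarcomere and Z-disc, calcium handling, potassium and sodium channels with connexin, extracellular matrix, TGF-beta pathway, pro-apoptotic and anti-apoptotic genes, fatty acid oxidation and PPAR targets, oxidative phosphorylation, citric acid cycle, glycolysis and glucose uptake, IGF and insulin signalling, angiogenesis and hypoxia, immediate early and tissue stress genes, endoplasmic reticulum stress, and cell cycle. They were written from general knowledge, and 21 genes stand in more than 1 list. Lists with at least 5 tested genes, 26 of them, were compared with the other genes by camera of limma with a preset correlation of 0.01, adjusted over the lists of a comparison. camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. With the preset correlation camera called 2, 14, 11, 9 and 4 lists in the order above, with an estimated correlation 0, 4, 3, 3 and 0, and fry 2, 15, 17, 11 and 0. At an unadjusted p under 0.05 with the preset correlation, camera gave 7 lists in sham and 8 for the interaction.

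Genes were named by a rule: the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (no such requirement for the interaction), leaving out clone-type names, then 2 to 4 called members of each list with the largest change, or 1 or 2 members as values where none was called, and always Gata4 and Gata6. Genes named for another reason are said to have been chosen after their values were seen. Of 57 named calls of genes with other probe sets, 0 had a probe set of opposite sign with an unadjusted limma p under 0.05.

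The fit was tested on simulated data with known changes and independent normal noise for each gene. Correlation between genes and arrays far from their group were not simulated, so these rates need not hold for the real arrays. At a log2 change of 1 it recovered 94.0% of changed genes in sham, 94.0% for TAC in wild type, 95.5% for TAC in G4D, 97.0% after TAC and 83.6% for the interaction. At 0.5 it recovered 47.8%, 53.7%, 52.2%, 61.2% and 23.9%. False calls made up 4.68%, 5.49%, 3.39%, 4.76% and 7.19% of calls.

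Alternatives tried were no filter, a filter at the 60th percentile, the values as deposited, the mean of a gene's probe sets, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, camera with an estimated correlation, and leaving out each array. Chosen after seeing the data were median centring, an offset of 16 on the linear scale, leaving out 3 arrays in doubt (G4D sham samples 3 and 5 and G4D TAC sample 4), and leaving out each array with the probe sets kept. The last was run for the named genes, since leaving out an array otherwise repeated the filter and the choice of the brightest probe set. A covariate for sex was not used, since every array had Y-linked transcripts (7.47 to 8.30) and low Xist (3.85 to 5.97).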

Results

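RNA was measured in 21 samples of mouse heart in 4 groups: wild-type mice after a sham operation (n = 4) or after TAC (n = 6), and G4D mice after a sham operation (n = 5) or after TAC (n = 6). TAC, transverse aortic constriction, narrows the aorta with a ligature and puts the left side of the heart under pressure. In the sham operation the aorta was left alone. G4D was read as the gene-targeted genotype with reduced Gata4, a zinc-finger transcription factor of heart muscle, which the series design sets against wild type at baseline and under pressure overload. The median of the deposited log2 values of an array lay between 4.31 and 5.33, and the correlation of an array with the mean of the rest of its group was at least 0.969. The number of arrays limits the precision of every value. Values after ± are standard errors of a log2 fold change unless called SD.

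Gata4 itself was read by a pair of probe sets, and neither passed the test for a difference between the genotypes. On the brighter probe set its level was 8.11 ± 0.15 (SD, n = 4) in wild-type sham, 7.85 ± 0.09 (SD, n = 5) in G4D sham, 7.80 ± 0.23 (SD, n = 6) in wild-type TAC and 7.97 ± 0.18 (SD, n = 6) in G4D TAC. The log2 fold change of G4D over wild type was -0.25 ± 0.12 in sham (adjusted p = 0.611) and 0.17 ± 0.10 after TAC (adjusted p = 0.556). On the dimmer probe set, in a fit of all probe sets, the same differences were -0.07 ± 0.31 and 0.07 ± 0.27. Where either probe set lies relative to the targeted part of the gene was not known, so these values do not check the genotype labels. Gata6, the other main GATA factor of adult heart muscle, did not pass the test between the genotypes either, at 0.07 ± 0.11 in sham (adjusted p = 0.94) and -0.17 ± 0.10 after TAC (adjusted p = 0.541). In the fit of all probe sets its others gave 0.19 ± 0.18 and -0.04 ± 0.28 in sham, and -0.37 ± 0.16 and 0.03 ± 0.24 after TAC. The TAC effect on Gata4 was -0.31 ± 0.12 in wild type (adjusted p = 0.125) and 0.12 ± 0.11 in G4D (adjusted p = 0.486), neither past the threshold.

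**Figure D1:**
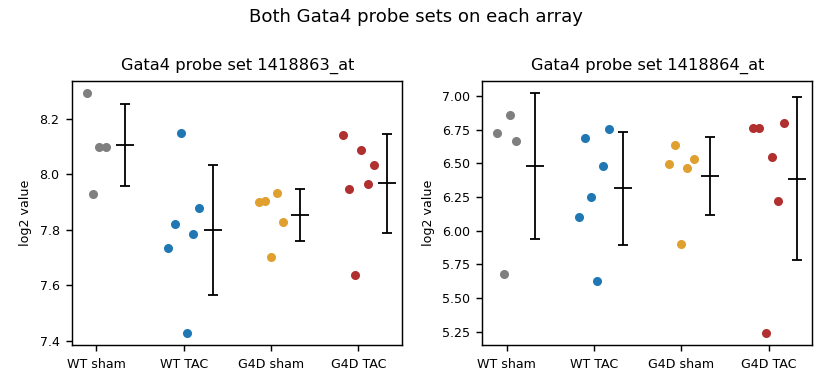
Quantile-normalized log2 value of both Gata4 probe sets on each array (points) by group, with the group mean and SD (black bars). On the brighter probe set, 1418863_at, the means were 8.11 in wild-type sham and 7.85 in G4D sham, and on both probe sets the groups overlapped after TAC.

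The first comparison asked how G4D hearts differed from wild-type hearts without pressure overload, and limma called 7 of 13279 tested genes. Myot, which encodes the Z-disc protein myotilin, was higher in G4D sham by 1.35 ± 0.21 (adjusted p = 0.00922), and Ankrd1, a stress-responsive cofactor of heart muscle, by 0.95 ± 0.15 (adjusted p = 0.00922). Ccn2, the connective tissue growth factor of the TGF-beta pathway, was higher by 1.31 ± 0.23 (adjusted p = 0.0305). The other called gene that was higher falls under the naming rule but is not used here. Klhdc8a, a kelch-domain gene, was lower by the largest amount of the 7, -1.67 ± 0.21 (adjusted p = 0.00172), and Tnfaip2, a gene induced by tumour necrosis factor, was lower at -1.02 ± 0.16 (adjusted p = 0.00922). On the lower side also stood Gm26782, at -1.31 ± 0.22 (adjusted p = 0.0164); it falls outside the naming rule and was chosen after its values were seen.

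Among the gene lists, the fetal and hypertrophic genes, which embryonic heart muscle expresses and the loaded adult heart switches back on, were higher in G4D sham by a median of 0.19 over 12 genes (adjusted p = 0.00309; adjusted p = 0.37 with an estimated correlation). Of these, 1 was called, Ankrd1; Myh7, the slow myosin heavy chain, stood at 1.61 ± 0.40 (adjusted p = 0.213). Fibroblast markers were higher by a median of 0.13 over 19 genes (adjusted p = 0.0156; adjusted p = 0.879 with an estimated correlation), with no member called. Mfap4 of elastic fibres stood at 0.96 ± 0.38 and Serpinf1, a secreted serpin, at 0.35 ± 0.15. In the values as deposited, in which the median of all genes shifted by -0.28, both lists had medians below 0, -0.10 and -0.20, or 0.18 and 0.07 relative to all genes, and after median centring, with a shift of -0.12, they stood at 0.05 and -0.05. The fetal list was called under both settings and the fibroblast list in the values as deposited alone. Sample 5 of G4D sham carried high levels of atrial genes, such as Myl7 and Myl4, the atrial myosin light chains, and of Car3, a carbonic anhydrase of fat and muscle. Their group differences were 1.04 ± 1.05, 0.92 ± 0.80 and 0.98 ± 0.81 with all arrays, and -0.35, -0.17 and -0.18 without it, and that of Mfap4 fell to 0.60. Without that array neither list was called, and the medians were 0.08 for the fetal list and 0.03 for the fibroblast list. The fibroblast list was not called without wild-type sham sample 4 (0.13) or G4D sham sample 4 (0.12) either. Matrix genes had a median of 0.05 (adjusted p = 0.374), with Thbs4 at 1.04 ± 0.30 and Timp3 at 0.90 ± 0.17. Fatty acid oxidation genes had a median of -0.07 (adjusted p = 0.1), with Angptl4 at -0.69 and Ucp3 at -0.68. Adjusted over the list alone, 4 fetal genes were higher and 1 lower, 3 matrix genes were higher, 1 TGF-beta gene was higher and 0 fibroblast markers were. The 17 tested genes reported as direct targets of Gata4 had a median of 0.02 (adjusted p = 0.801), Nppa among them at 0.52 ± 0.38, or 0.029 without G4D sham sample 5, and 1 was higher adjusted over the list alone.

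Counted by separation alone, 385 genes (2.90%) had sham groups that did not overlap, where chance gives 1.59%, and 1074 genes had an unadjusted p under 0.05. The count was 1 without wild-type sham sample 1 or sample 2 and 27 without G4D sham sample 2. Leaving out either of the former ended the calls of Myot (1.19 to 1.56 over the arrays left out), Ankrd1 (0.86 to 1.09), Tnfaip2 (-1.12 to -0.91), Ccn2 (1.19 to 1.42) and Gm26782, and the latter pair also lost theirs without 4 other arrays each. With the values as deposited 3 genes were called, 0 of them higher in G4D, so that the calls of Myot, Ccn2 and Ankrd1 ended, and with median centring 4, 1 of them higher.

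The second comparison asked how wild-type hearts responded to pressure overload, and 976 genes were called, 689 higher and 287 lower after TAC. Genes of cell division were among the largest rises: Cdk1, the kinase that drives entry into mitosis, by 3.23 ± 0.30 (adjusted p = 4.83e-06), the topoisomerase gene Top2a by 2.97 ± 0.39 and the proliferation marker Mki67 by 2.86 ± 0.36. The wild-type sham means of these 3 genes, 3.67, 4.05 and 4.22, lay below 4.35, the level required of a mean over all arrays, so the size and rank of their rises are imprecise. Matrix genes rose as well, with Postn, which encodes the matricellular protein periostin, up by 2.62 ± 0.30 (adjusted p = 4.43e-05) and Timp1, an inhibitor of matrix proteases, by 2.60 ± 0.32. The fetal program rose with Myh7 by 2.12 ± 0.38 (adjusted p = 0.00173), the natriuretic peptide gene Nppa by 1.66 ± 0.37, Ankrd1 by 1.64 ± 0.15 and the skeletal actin gene Acta1 by 1.46 ± 0.27. The largest falls were of Retnla, which encodes a resistin-like protein of macrophages, -1.61 ± 0.41, and the anoctamin gene Ano10, -1.35 ± 0.25.

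Of the other genes with the largest rises, Kif22, a mitotic kinesin, Smc2, a condensin subunit, Cks2, a partner of cyclin-dependent kinases, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 2.94, 2.62, 2.50 and 2.48, and the amino acid transporter gene Slc36a3 by 2.75. Without wild-type sham sample 4 the rise of Slc36a3 was 1.69, and like it Smc2, Cks2 and Ube2c had wild-type sham means below 4.35 (2.04, 3.49, 4.19 and 3.33), so the sizes are imprecise. The other large falls were of the galectin gene Lgals4 (-1.26), the potassium channel subunit gene Kcnv2 (-1.22), the carboxylesterase gene Ces1d (-1.03), the vessel-stabilising ligand Angpt1 (-0.90), the orphan receptor gene Gpr22 (-0.85), Fah of tyrosine breakdown (-0.83), the kinase gene Wnk2 (-0.81) and the ephrin receptor gene Epha4 (-0.80).

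Extracellular matrix genes rose together in wild type, 30 of 39 with a median of 0.99 (adjusted p = 6.92e-35), including Tnc, the matrix glycoprotein tenascin C, by 2.48 ± 0.43 from a sham mean of 3.04, below 4.35. Cell cycle genes rose in 20 of 23 with a median of 1.15 (adjusted p = 6.31e-26), and fetal and hypertrophic genes in 9 of 12 with a median of 0.94 (adjusted p = 2.33e-10). Macrophage and myeloid markers rose in 14 of 24 with a median of 0.62 (adjusted p = 2.81e-15), among them the lysosomal genes Cd68 by 1.04 and Ctss by 1.02. These 4 lists kept their call with an estimated correlation, with adjusted p = 0.0272 for matrix, cell cycle and fetal genes and 0.0419 for macrophage markers. Fibroblast markers, which share 3 collagen genes with the matrix list, rose in 10 of 19 and fell in 1, with Mfap4 of elastic fibres up by 2.04 and Col1a1 by 1.58. Their median was 0.69 (adjusted p = 1.91e-09; adjusted p = 0.0714 with an estimated correlation). Endothelial markers rose in 5 of 19, with Cd34 up by 0.80 and Icam2 by 0.66. Their median was 0.13 (adjusted p = 0.000797; adjusted p = 0.287 with an estimated correlation). TGF-beta pathway genes rose in 7 of 26, with Ltbp2, a binding protein of the microfibrils, up by 2.38 from a sham mean of 3.45 and Ccn2 by 1.36. Their median was 0.29 (adjusted p = 7.03e-06; adjusted p = 0.0959 with an estimated correlation). Immediate early and stress genes rose in 4 of 24, with Ier5 up by 0.87 and the transcription factor gene Atf3 by 0.81. Their median was 0.34 (adjusted p = 8.83e-05; adjusted p = 0.0714 with an estimated correlation).

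Lists of energy supply and excitation were lower after TAC in wild type. Fatty acid oxidation genes fell in 3 of 28, with Mlycd, which removes malonyl-CoA, at -0.64 and the dehydrogenase gene Acads at -0.41. Their median was -0.23 (adjusted p = 8.88e-07; adjusted p = 0.0714 with an estimated correlation). Oxidative phosphorylation genes fell in 1 of 32, Cox7a1 at -0.32. Their median was -0.09 (adjusted p = 0.00124; adjusted p = 0.287 with an estimated correlation). Citric acid cycle genes had no called member, with Suclg2 at -0.30 and Dlst at -0.26. Their median was -0.13 (adjusted p = 0.00124; adjusted p = 0.223 with an estimated correlation). Channel and connexin genes fell in 3 of 14, with Kcnv2 and the background potassium channel gene Kcnk3 (-0.65) among them. Their median was -0.35 (adjusted p = 0.000797; adjusted p = 0.0714 with an estimated correlation). Calcium handling genes fell in 1 of 16, the channel subunit gene Cacnb2 at -0.52. Their median was -0.15 (adjusted p = 0.042; adjusted p = 0.0714 with an estimated correlation). Cardiac transcription factors had no called member, with Myocd at -0.53, Tbx5 at -0.40 and Gata6 at -0.15. Their median was -0.11 (adjusted p = 0.0203; adjusted p = 0.0714 with an estimated correlation). Adjusted over the list alone, 34 matrix, 20 cell cycle, 10 fetal, 17 macrophage, 11 fibroblast, 7 endothelial, 9 TGF-beta and 7 immediate early genes were higher, and 8 fatty acid oxidation, 1 oxidative phosphorylation, 0 citric acid cycle, 8 channel, 1 calcium handling and 0 transcription factor genes lower.

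In wild type 1391 genes (10.5%) had sham and TAC groups that did not overlap, where chance gives 0.952%, and 440 of the called genes changed at least 1.5-fold. The 3'-to-5' difference of the actin probe sets, a sign of RNA quality, was 0.52 ± 0.10 (SD, n = 4) in wild-type sham and 0.32 ± 0.11 (SD, n = 6) in wild-type TAC. The groups did not overlap on it (lowest sham 0.437, highest TAC 0.408), so by this measure RNA quality and the operation cannot be told apart. That of the Gapdh probe sets overlapped. Leaving out wild-type TAC sample 4 ended the calls of Retnla (-1.41), Ces1d (-0.85), Epha4 (-0.76), Acads (-0.36), Cacnb2 (-0.52) and Cox7a1 (-0.27). Wild-type sham sample 1 ended all of these but Cox7a1, and that of Angpt1 (-0.84), and other wild-type arrays ended some of them too. The calcium handling list was not called without wild-type sham sample 1, 2 or 4 or wild-type TAC sample 1, 2 or 3 (-0.18 to -0.10). The count fell to 564 without wild-type sham sample 1 and to 598 without wild-type TAC sample 4. Of 40 named calls of this comparison 21 were kept in the values as deposited, where Slc36a3 did not pass the filter and those of Nppa, Cd68, Ctss, Cd34, Icam2, Ier5, Atf3, Mlycd, Acads, Kcnk3, Cacnb2, Cox7a1, Ces1d, Angpt1, Gpr22, Fah, Wnk2 and Epha4 ended. With the values as deposited 95 genes were called, 94.7% of them higher against 70.6% here, and with median centring 388, 93.8% of them higher.

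The third comparison asked how G4D hearts responded to pressure overload, and 2985 genes were called, 1748 higher and 1237 lower after TAC. Matrix and matrix-binding genes were among the largest rises: Tnc by 4.06 ± 0.40 (adjusted p = 6.91e-07), the cartilage intermediate layer gene Cilp by 4.01 ± 0.32, Ltbp2 by 3.86 ± 0.32 and Postn by 3.42 ± 0.29. The G4D sham means of Tnc and Ltbp2, 2.54 and 3.42, lay below 4.35, so the size and rank of their rises are imprecise. Nmrk2, a kinase of muscle that makes NAD from nicotinamide riboside, rose by 3.85 ± 0.36 (adjusted p = 3.99e-07), and Tgfb2, a ligand of the TGF-beta pathway, by 2.51 ± 0.22 (adjusted p = 1.67e-07). The carboxylesterase gene Ces1d fell by the largest amount, -2.37 ± 0.28 (adjusted p = 4.47e-06), followed by the methyltransferase gene Inmt at -2.25 ± 0.38 and Ano10 at -2.15 ± 0.23.

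Of the other genes with the largest rises, Cthrc1, a secreted protein of collagen-making cells, rose by 3.33, Timp1 by 3.25, Ube2c by 2.91, Cdk1 by 2.90 and Lox, which cross-links collagen, by 2.80. The G4D sham means of Cthrc1, Timp1, Ube2c and Cdk1 and the G4D TAC mean of Retnla lay below 4.35 as well (2.96, 4.32, 2.77, 3.95 and 3.15). Retnla, Lgals4, Kcnv2, the ephrin gene Efnb3 and the phosphatase gene Dusp18 fell by 1.96, 1.67, 1.66, 1.55 and 1.53. Hlf, a transcription factor with a daily rhythm, was among the largest falls at -1.67 ± 0.28 (adjusted p = 0.000206), and its relative Tef, chosen after its values were seen, stood at -0.88. The mean level of 9 clock genes that peak towards evening, a set chosen after Hlf was seen, was 7.52 ± 0.24 (SD, n = 5) in G4D sham, 6.65 ± 0.41 (SD, n = 6) in G4D TAC and 6.84 ± 0.28 (SD, n = 4) in wild-type sham. The channel gene Kcnj3, richest in atria, fell by 1.58, beside Stard10 at -1.36 and Tbx5 at -1.10 of the atrial list. Without G4D sham sample 5, which carried high atrial genes, they stood at -1.27, -0.92 and -0.88 and stayed called.

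Extracellular matrix genes rose in 35 of 39 and fell in 1, with a median of 1.49 (adjusted p = 8.9e-31; adjusted p = 0.0469 with an estimated correlation). Fetal and hypertrophic genes rose in 11 of 12, with Rcan1, a feedback inhibitor of calcineurin, up by 2.08 ± 0.21 and the Z-disc gene Synpo2l by 1.88 ± 0.14. Their median was 1.43 (adjusted p = 7.78e-12; adjusted p = 0.0207 with an estimated correlation). Fatty acid oxidation genes fell in 20 of 28, with the uncoupling protein gene Ucp3 at -1.0 ± 0.26 and the thiolase gene Acaa2 at -0.89 ± 0.13. Their median was -0.44 (adjusted p = 8.01e-11; adjusted p = 0.0469 with an estimated correlation). The other called lists lost their call with an estimated correlation. Cell cycle genes rose in 20 of 23, Top2a by 2.67 from a sham mean of 4.07. Their median was 1.02 (adjusted p = 1.02e-13; adjusted p = 0.0963 with an estimated correlation). Fibroblast markers rose in 12 of 19 and fell in 2, with Mfap4 up by 2.37 and Col1a1 by 2.07. Their median was 0.77 (adjusted p = 3.06e-07; adjusted p = 0.139 with an estimated correlation). Macrophage and myeloid markers rose in 15 of 24, with the chemokine receptor gene Cx3cr1 up by 2.01 from a sham mean of 3.62 and Cd68 by 1.23. Their median was 0.54 (adjusted p = 1.24e-07; adjusted p = 0.139 with an estimated correlation). TGF-beta pathway genes rose in 12 of 26 and fell in 1. Their median was 0.36 (adjusted p = 2.87e-05; adjusted p = 0.139 with an estimated correlation). Immediate early and stress genes rose in 10 of 24 and fell in 2, with Egr1 and Junb both up by 1.17. Their median was 0.32 (adjusted p = 0.000676; adjusted p = 0.139 with an estimated correlation).

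Channel and connexin genes fell in 8 of 14, with Kcnv2 and Kcnj5, a subunit of the acetylcholine-gated potassium channel (-1.04), among them. Their median was -0.40 (adjusted p = 0.000124; adjusted p = 0.0601 with an estimated correlation). Citric acid cycle genes fell in 9 of 15, with Suclg2 at -0.51 and Idh2 at -0.38 (median -0.22, adjusted p = 8.02e-06; adjusted p = 0.13 with an estimated correlation), and oxidative phosphorylation genes in 9 of 32, with Cox7a1 at -0.39 and Sdha at -0.36. Their median was -0.11 (adjusted p = 0.000247; adjusted p = 0.221 with an estimated correlation). In the values as deposited, in which the median of all genes shifted by 0.31, the citric acid cycle and oxidative phosphorylation medians turned to 0.11 and 0.12 and stood at -0.20 and -0.18 relative to that of all genes. Adjusted over the list alone, 35 matrix, 11 fetal, 21 cell cycle, 14 fibroblast, 16 macrophage, 13 TGF-beta and 11 immediate early genes were higher, and 21 fatty acid oxidation, 9 channel, 12 citric acid cycle and 9 oxidative phosphorylation genes lower.

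The reported direct targets of Gata4 held 3 genes of the fetal list and were not called as a list after TAC in G4D (6 higher and 2 lower of 17, median 0.13, adjusted p = 0.0506), although the natriuretic peptide genes Nppa and Nppb rose by 1.69 and 1.66, Myh7 by 1.44 and the survival gene Bcl2 by 1.23. Without G4D sham sample 5, which carried high atrial genes, the rise of Nppa was 2.18. Among cardiac transcription factors Tbx5, Hand2 at -0.55 and Gata6 at -0.38 fell (0 higher and 3 lower of 20, median -0.03, adjusted p = 0.457). Gata6 stood at 0.039 in the values as deposited, or -0.27 relative to all genes. Sarcomere and Z-disc genes moved both ways, with the intermediate filament gene Des up by 0.74 and the titin cap gene Tcap at -0.62 (4 higher and 5 lower of 21, median 0.03, adjusted p = 0.89). The mean level of the sarcomere list was 12.03 in both G4D sham and G4D TAC. Pro-apoptotic genes moved both ways as well, with Bok up by 1.16 and Bcl2l11 at -0.77 (8 higher and 2 lower of 28, median 0.10, adjusted p = 0.182), and anti-apoptotic genes rose in 4, Birc5, also a gene of mitosis, by 2.22 from a sham mean of 3.36 (of 15, median 0.05, adjusted p = 0.183). None of the remaining lists was called in G4D. Calcium handling genes were 1 higher and 5 lower of 16, median -0.07, adjusted p = 0.186. Glycolysis and glucose uptake genes were 3 higher and 4 lower of 17, median 0.15, adjusted p = 0.595. IGF and insulin signalling genes were 2 higher and 5 lower of 19, median -0.17, adjusted p = 0.402. Angiogenesis and hypoxia genes were 3 higher and 4 lower of 17, median -0.05, adjusted p = 0.838, and their mean level was 7.42 in both G4D sham and G4D TAC. Endoplasmic reticulum stress genes were 5 higher and 2 lower of 21, median 0.10, adjusted p = 0.484. Endothelial markers were 2 higher and 0 lower of 19, median 0.09, adjusted p = 0.333, and smooth muscle and pericyte markers 2 higher and 1 lower of 12, median 0.03, adjusted p = 0.651. Lymphocyte markers were 1 higher and 1 lower of 6, median -0.05, adjusted p = 0.989, with a mean of 0.08. Atrial markers were 2 higher and 3 lower of 11, median -0.88, adjusted p = 0.182, and this median rests on G4D sham sample 5, without which it was 0.010. Adipocyte markers were 0 higher and 2 lower of 6, median -0.53, adjusted p = 0.119. Car3 among them stood at -0.59, or 0.57 without G4D sham sample 5. Erythroid markers, with 3 tested genes of median -0.28, and epicardial markers, with 4 of median 0.04 and mean -0.08, were too few for the list test.

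In G4D 1343 genes (10.1%) had sham and TAC groups that did not overlap, where chance gives 0.433%, and 1029 of the called genes changed at least 1.5-fold. The actin 3'-to-5' difference was 0.46 ± 0.10 (SD, n = 5) in G4D sham and 0.25 ± 0.08 (SD, n = 6) in G4D TAC. These groups did not overlap on it either (lowest sham 0.385, highest TAC 0.379), while they did on that of Gapdh. All 51 named calls of this comparison were kept when each array was left out in turn, and 39 of them in the values as deposited, where those of Ucp3, Acaa2, Suclg2, Idh2, Cox7a1, Sdha, Kcnj5, Hand2, Gata6, Bcl2l11, Tcap and Tef ended. With the values as deposited 2252 genes were called, 97.8% of them higher against 58.6% here, and with median centring 2178, 88.8% of them higher.

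**Figure D2:**
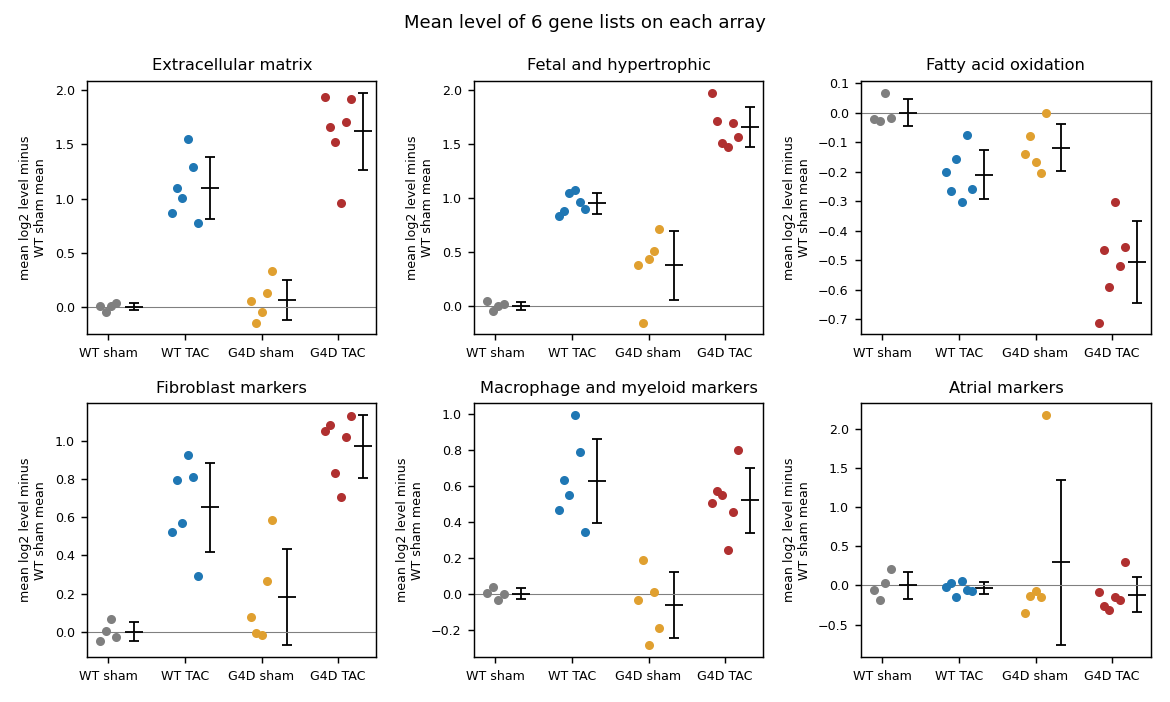
Mean quantile-normalized log2 level of 6 gene lists on each array (points), less the mean of the wild-type sham arrays, with the group mean and SD (black bars). The matrix list stood between 0.78 and 1.55 on the wild-type TAC arrays and between 0.96 and 1.94 on the G4D TAC arrays, and the atrial list stood at 2.18 on G4D sham sample 5.

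The responses of both genotypes to TAC ran in the same direction, with a Pearson correlation of 0.723 (Spearman 0.602) between their log2 fold changes across the 13279 genes, which are not independent replicates. With no filter on dim probe sets the Pearson correlation was 0.441. Of the genes higher after TAC in wild type, 599 were also called higher in G4D, against 90.7 if the calls were independent, and of the lower ones 227, against 26.7. Among them were Postn, Tnc, Timp1, Cdk1 and Ltbp2, higher in both, and Ces1d, Ano10, Retnla, Lgals4 and Kcnv2, lower in both. Of the genes called in wild type, 98.7% of the higher and 97.6% of the lower ones had the same sign in G4D. The compared effects share no array, and the jackknife standard error of the correlation over arrays was 0.0557. In both genotypes the sham and TAC arrays did not overlap on the actin 3'-to-5' difference. By this measure RNA quality and the operation cannot be told apart for the correlation either.

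The fourth comparison asked how G4D hearts differed from wild-type hearts under pressure overload, and 446 genes were called, 279 higher and 167 lower in G4D. Matrix genes led the higher side: Thbs4, a thrombospondin induced in injured heart, was higher by 2.68 ± 0.26 (adjusted p = 6.8e-06), Cilp by 2.50 ± 0.31 and Comp, a relative of Thbs4, by 1.52 ± 0.26. Tgfb2 was higher by 1.83 ± 0.21 (adjusted p = 2.4e-05), Nmrk2 by 2.21 ± 0.34 and the LIM-domain gene Fhl1, a partner of titin, by 1.32 ± 0.13 (adjusted p = 6.8e-06). Efnb3 was lower at -1.70 ± 0.18 (adjusted p = 1.53e-05), and so were Acot1, a thioesterase of fatty acyl-CoA, at -1.58 ± 0.35 and Fbp2, the fructose bisphosphatase of muscle, at -1.12 ± 0.21. Myot and Ccn2 were higher after TAC as well, by 1.66 ± 0.18 and 1.35 ± 0.20, and Klhdc8a lower at -1.0 ± 0.18. Of the genes called in sham, 2 of 4 higher and 2 of 3 lower ones were called the same way after TAC. Tnfaip2, lower in G4D sham, had means of 7.90 in wild-type TAC and 7.73 in G4D TAC.

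The growth factor gene Fgf6, the adaptor gene Bex1 and the adhesion gene Svep1 were higher by 1.68, 1.56 and 1.38. On the lower side stood the collectin gene Colec11 (-1.19), the ring-finger gene Rnf207 (-1.11), Kcnj3 (-1.07), the phosphodiesterase gene Pde1c (-0.96), the carbonic anhydrase gene Car14 (-0.93) and H2-Ab1, a chain of the MHC class II complex (-0.91). The wild-type TAC mean of Fgf6 and the G4D TAC mean of Acot1, 4.07 and 3.97, lay below 4.35, so these sizes are imprecise.

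**Figure D3:**
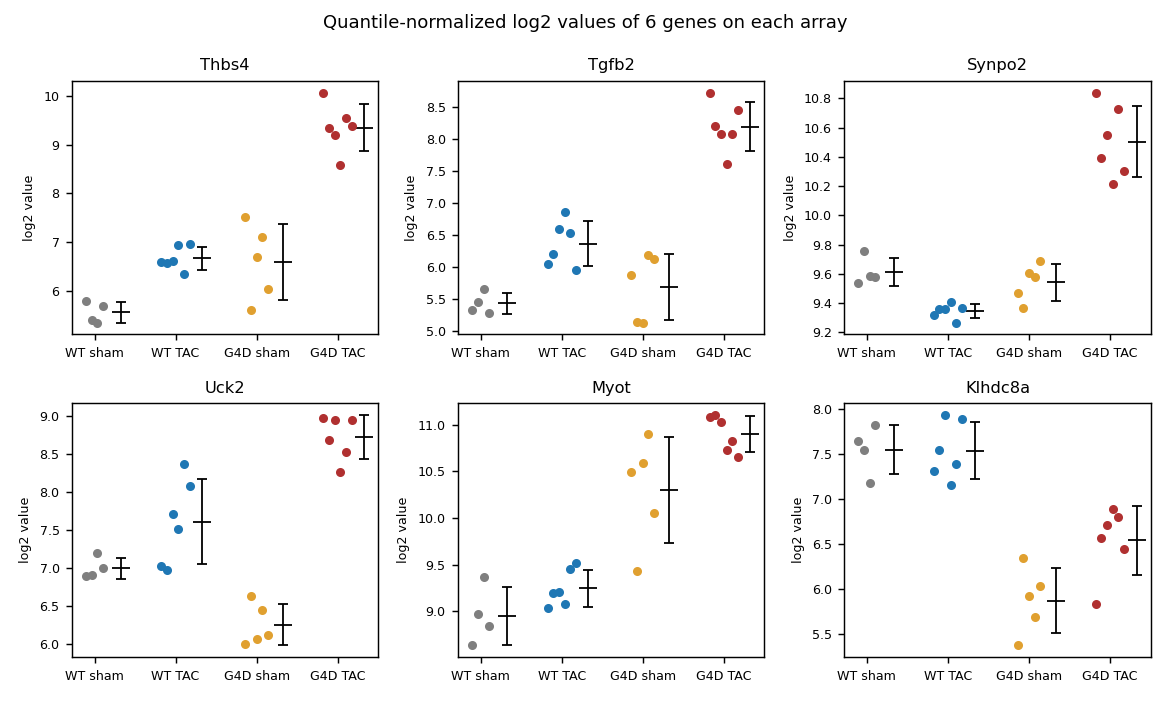
Quantile-normalized log2 value of 6 genes on each array (points) by group, with the group mean and SD (black bars). Thbs4, Tgfb2 and Myot are among the genes with the largest rises in G4D over wild type after TAC, Synpo2 and Uck2 are those called in the test of the difference between the TAC effects, and Klhdc8a was lower in G4D in both operations.

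Fetal and hypertrophic genes were higher in G4D than in wild type after TAC in 6 of 12, with Rcan1 higher by 1.28 ± 0.20 and Uchl1, a ubiquitin hydrolase, by 1.16 ± 0.18. Their median was 0.64 (adjusted p = 2.89e-14; adjusted p = 0.00809 with an estimated correlation). Fatty acid oxidation genes were lower in 7 of 28, with Ucp3 at -1.03 ± 0.25 and Acaa2 at -0.63 ± 0.12 (median -0.28, adjusted p = 2.89e-14; adjusted p = 0.0229 with an estimated correlation), and channel and connexin genes in 4 of 14, with Kcnj5 at -0.84 and the transient outward channel gene Kcnd2 at -0.65. Their median was -0.37 (adjusted p = 1.41e-05; adjusted p = 0.0317 with an estimated correlation). The other 6 called lists lost their call with an estimated correlation. Extracellular matrix genes were higher in 7 of 39, with the collagen gene Col8a1 higher by 1.12 ± 0.20 (median 0.45, adjusted p = 1.58e-15; adjusted p = 0.189 with an estimated correlation), and fibroblast markers in 4 of 19, with Mfap4 higher by 1.29 and Serpinf1 by 0.97. Their median was 0.23 (adjusted p = 1.71e-05; adjusted p = 0.305 with an estimated correlation). TGF-beta pathway genes were higher in 4 of 26, with Ltbp2 higher by 1.46. Their median was 0.09 (adjusted p = 0.00114; adjusted p = 0.316 with an estimated correlation). Glycolysis genes were higher in 2 of 17 and lower in 1, with the platelet phosphofructokinase gene Pfkp higher by 0.95 and the muscle enolase gene Eno3 at -0.39. Their median was 0.10 (adjusted p = 0.0279; adjusted p = 0.215 with an estimated correlation).

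Citric acid cycle genes were lower in G4D after TAC in 1 of 15, Idh2 at -0.33 (median -0.14, adjusted p = 1.41e-05; adjusted p = 0.189 with an estimated correlation), and oxidative phosphorylation genes had no called member, with Sdha and Ndufv1 both at -0.16. Their median was -0.07 (adjusted p = 0.00104; adjusted p = 0.342 with an estimated correlation). In the values as deposited, with a shift of 0.14 in the median of all genes, these lists had medians of 0.00 and 0.03, or -0.14 and -0.11 relative to all genes. Endothelial markers had a median of -0.09 (adjusted p = 0.244) and macrophage markers of -0.12 (adjusted p = 0.05). The reported direct targets of Gata4 were not called as a list (median 0.02, adjusted p = 0.242), with Bcl2 higher by 0.78 and the transcription factor gene Hand2 lower at -0.42. Adjusted over the list alone, 15 matrix, 9 fetal, 6 fibroblast, 6 TGF-beta, 5 glycolysis and 2 Gata4 target genes were higher, and 15 fatty acid oxidation, 8 channel, 2 citric acid cycle, 0 oxidative phosphorylation, 2 glycolysis and 2 TGF-beta genes lower.

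After TAC 344 genes (2.59%) had genotype groups that did not overlap, where chance gives 0.216%, and 183 of the called genes differed at least 1.5-fold. Leaving out G4D TAC sample 1 ended the calls of Mfap4 (1.16), Ucp3 (-0.88), Kcnj5 (-0.77), Kcnd2 (-0.55), Idh2 (-0.30) and Hand2 (-0.42), and each of them also ended without wild-type TAC sample 3 and without 3 or more other arrays. The call of H2-Ab1 ended without wild-type TAC sample 2 (-0.81). The glycolysis list was not called after median centring (0.11), nor without wild-type TAC sample 4 or G4D TAC sample 2 (0.08 each). The count fell to 247 without G4D TAC sample 1, to 281 without wild-type TAC sample 3 and to 284 without wild-type TAC sample 1. Of 38 named calls of this comparison 23 were kept in the values as deposited, where those of Colec11, Kcnj3, Klhdc8a, Pde1c, Car14, Ucp3, Acaa2, Kcnj5, Kcnd2, Idh2, Eno3, Hand2, H2-Ab1 and 2 other MHC class II genes ended. With the values as deposited 64 genes were called, 87.5% of them higher against 62.6% here, and with median centring 185, 82.7% of them higher. Without the 3 arrays in doubt there were 705.

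The last comparison asked whether the response to TAC itself differed between the genotypes, and 2 genes were called. Synpo2, which encodes an actin-binding protein of the Z-disc, had a TAC effect larger in G4D by 1.23 ± 0.14 (adjusted p = 0.000356), with effects of -0.27 in wild type and 0.96 in G4D. Uck2, a kinase that salvages uridine and cytidine, had a TAC effect larger in G4D by 1.85 ± 0.31 (adjusted p = 0.0359), with effects of 0.61 and 2.46. At an unadjusted p under 0.05 there were 1110 genes. The probe sets of Synpo2 differed: beside the one tested, the next brightest gave 0.95 and a dimmer one -0.01, which stood at -0.53 after TAC in G4D, opposite in sign to the one tested. The other probe sets of Uck2 ran from 0.47 to 1.86. With the mean of a gene's probe sets neither gene was called, and Uck2 was not called with no filter on dim probe sets or with the replicate block either. Among genes named in the comparisons above, the difference was 1.54 ± 0.30 for Rcan1 (adjusted p = 0.0746), 2.42 ± 0.52 for Nmrk2 (adjusted p = 0.0873), chosen after its values were seen, and 0.42 ± 0.16 for Gata4 (adjusted p = 0.432). For Gata6 it was -0.23 ± 0.15 (adjusted p = 0.729), and its other probe sets gave -0.55 ± 0.24 and 0.07 ± 0.36.

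Matrix genes had a larger TAC effect in G4D, with a median difference of 0.44 (adjusted p = 8.15e-08; adjusted p = 0.732 with an estimated correlation), Thbs4 at 1.64 ± 0.40 and Tnc at 1.58 ± 0.59, an imprecise size since both sham means of Tnc, 3.04 and 2.54, lay below 4.35. The fetal and hypertrophic genes had a larger TAC effect in G4D as well by their median, at 0.44 (adjusted p = 0.00111; adjusted p = 0.566 with an estimated correlation), Uchl1 at 0.98 ± 0.28. Not every member followed: Ankrd1 stood at -0.65 (limma adjusted p = 0.301), and the rise of Myh7 given above was smaller in G4D than in wild type. Fatty acid oxidation genes stood lower at -0.17 (adjusted p = 2.73e-05; adjusted p = 0.566 with an estimated correlation), with Slc27a1 at -0.58 and Ppargc1a at -0.64, neither called, the latter at -0.34 without wild-type sham sample 2 and, on the same probe set, -0.39 without wild-type TAC sample 5, and citric acid cycle genes at -0.07 (adjusted p = 0.0203; adjusted p = 0.741 with an estimated correlation), with Idh2 at -0.25 and Suclg2 at -0.21. In the values as deposited, in which the median of all genes shifted by 0.42, the latter medians were 0.31 and 0.41, and after median centring, with a shift of 0.15, 0.04 and 0.14. Relative to all genes they stood at -0.11 and -0.015 under both settings. Neither list was called under these settings. With an estimated correlation camera called 0 lists and fry called 0, and at an unadjusted p under 0.05 with the preset correlation there were 8. Adjusted over the list alone, 6 fetal genes were higher and 1 lower, 2 matrix genes higher and 1 lower, and 0 fatty acid oxidation and 0 citric acid cycle genes lower. The fetal list was not called without G4D sham sample 2 (0.29), and the citric acid cycle list not without wild-type TAC sample 3, G4D sham sample 1 or 2 or G4D TAC sample 6 (-0.07 to -0.06). Uck2 lost its call when any of 14 single arrays was left out (1.73 to 2.0), and the count was 29 without G4D TAC sample 4 and 5 without G4D TAC sample 2.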

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

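The tests of the atrial genes, of the matrix, fetal and fatty acid oxidation genes and of the fetal genes in sham were chosen only after the result was seen, whereas the screen for samples far from their group and the other splits of the samples were planned.

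Atrial genes and Car3 stood far above the other arrays of the group on G4D sham sample 5. Against the mean of the other 4 arrays Myl7 was higher by 6.94, Car3 by 5.82, Myl4 by 5.42, Nppa by 2.47, Stard10 by 2.21 and Tbx5 by 1.13, and the means of the atrial and adipocyte lists were higher by 2.36 and 1.23, the latter carried by Car3, since the median of the 6 adipocyte markers was 0.60. The array was picked for such genes. Of the 6 tested atrial markers that the screen did not single out there, 5 were also highest on it among the 5 G4D sham arrays. Their median rise was 0.81 (1.57 over all 11). The screen took single genes only where they are named here, so most of these 6 were not screened one by one. All 11 also enter the list mean that was flagged on this array, so the 5 of 6 is not independent of the choice. Atrial tissue in the sample is a candidate explanation. Fetal genes switched on in ventricular muscle would raise the other fetal genes by at least 50% of the 1.57, but these rose by a median of 0.29 over 11 genes. Reduced Gata4 would raise the atrial markers on the other 4 G4D sham arrays too, but these stood at -0.18 relative to wild-type sham (SD 0.17).

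After TAC the G4D samples had higher matrix and fetal genes and lower fatty acid oxidation genes than wild type, and with a score of 16 fibroblast markers in the fit the matrix median moved from 0.45 (quartiles 0.25 and 0.62, adjusted p = 1.58e-15; adjusted p = 0.189 with an estimated correlation) to 0.052 (quartiles -0.15 and 0.23, adjusted p = 0.2). More fibroblasts in the samples, or more active ones, may lie behind the matrix genes, and the score cannot separate these. The labels name cardiac myocytes and do not say whether cells were isolated, so a share in the samples need not be that of the heart. The score also holds matrix genes itself, such as Mfap4, so part of this fall was built in. The fatty acid oxidation median stayed at -0.22 (adjusted p = 1.53e-10), so what the score tracks did not account for most of that part, and the fetal median stayed at 0.46. A change in cell share that the score misses was not tested. A smaller muscle share that raised all other cell types alike would leave fibroblast markers level with the rest, but they rose over endothelial and macrophage markers by 0.39 (exact permutation p = 0.00216, 924 splits, two-sided). Muscle replaced by fibroblasts alone would give such a rise, so a smaller muscle share stays open. Where all genes shifted by 0.14, in the values as deposited, the matrix and fatty acid oxidation medians stood at 0.48 (quartiles 0.24 and 0.65) and -0.25 (-0.37 and -0.17) relative to all genes. Both lists stayed called there and after median centring, so quantile normalization was not what set them apart. A shift of whole arrays moves all genes alike and could not set lists apart, so these values do not test it. Scaling by level within the deposited values was not tested. The fatty acid oxidation median was below 0 in the values as deposited too, at -0.11 (quartiles -0.23 and -0.027), while the 0.62 of the matrix genes decides nothing, since the shift went the same way. The genotype and a difference in the severity of the constriction stay open and were not tested.

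In sham the fetal and hypertrophic list was higher in G4D by a median of 0.19 (adjusted p = 0.00309; adjusted p = 0.37 with an estimated correlation). Without G4D sham sample 5 the median was 0.077 (adjusted p = 0.0556), but without the 3 arrays in doubt, that one included, it was 0.10 and still called, so whether the array with atrial genes is the source stays open. Its quartiles were 0.12 and 0.61 with that array and 0.053 and 0.55 without it, and Nppa moved most, from 0.52 to 0.029, while Myh7 moved from 1.61 to 1.45 and Ankrd1 from 0.95 to 0.87. Where all genes shifted by -0.28, in the values as deposited, the median was 0.18 relative to all genes (quartiles 0.047 and 0.56). The list stayed called there and after median centring, so quantile normalization was not what set it above other genes. A shift of whole arrays moves all genes alike and could not do so, so these values do not test it. Whether the list rose above 0 stays open, since the median itself was -0.097 in the values as deposited (quartiles -0.23 and 0.28), as does reduced Gata4, which was not tested.

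Comp was also far from the group on G4D sham sample 5, higher by 1.35. On wild-type TAC sample 4, Cd68, Cilp, Postn and Myh7 were higher than the mean of the other arrays by 0.69, 0.84, 0.87 and 0.89, Ces1d and Cox7a1 stood at -1.04 and -0.28, and the Gata4 target list at 0.15. On G4D TAC sample 4, Postn, Col8a1 and Atf3 stood at -1.68, -1.16 and -0.79, Inmt at 1.92, Cox7a1 at 0.30 and the sarcomere list at 0.061. On wild-type sham sample 3, Mki67 stood at 0.56, Wnk2 at 0.26, Ltbp2 at -0.19, Retnla at -0.75 and the fatty acid oxidation list at 0.092. On G4D sham sample 2, Acta1 stood at -1.83 and Gm26782 at 1.40. On G4D TAC sample 6, Cd68 stood at 0.72 and Myl4 at 2.33, and on wild-type sham sample 1 Eno3 at -0.14 and Kcnv2 at -0.50. Of the rest, Fbp2 stood at -1.39 on G4D TAC sample 1, H2-Eb1 at -1.17 on G4D TAC sample 2, the Gata4 target list at -0.084 on G4D TAC sample 3 and the anti-apoptotic list at 0.13 on G4D sham sample 4. Gata6 stood at -0.26 on wild-type TAC sample 2, Hand2 at 0.58 on sample 6, Ppargc1a at 1.47 on sample 5 and Uchl1 at -0.75 on wild-type sham sample 2. In all, 41 of 568 tests found a sample far from its group, where chance gives about 1 in 20.

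The TAC effect differed between the genotypes by the test of the difference for Synpo2 (1.23) and Uck2 (1.85). The same test on lists gave medians of 0.44 for fetal genes, 0.44 for matrix genes, -0.17 for fatty acid oxidation and -0.065 for the citric acid cycle, and none was called with an estimated correlation (adjusted p = 0.566, 0.732, 0.566 and 0.741).

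Of 100 splits of the samples, the real one included, 2 gave as many called genes as the sham comparison (7, highest other 38 with 8 of 9 arrays exchanged, nearly the mirror of the real split), 1 as many as TAC in wild type (976, highest other 77), 2 as many as TAC in G4D (2985, highest other 3042, a split nearly the real one turned round with 10 of 11 arrays exchanged) and 1 as many as genotype after TAC (446, highest other 96). These counts passed the planned limit of fewer than 5 of 100 splits. For sham this is weak, since the split with 38 genes set 1 G4D sham array beside the wild-type ones and gave more than the real split. The sham count was also 1 without wild-type sham sample 1, so chance is not excluded for it. The correlation of the TAC effects (0.723, highest other 0.513), which 1 split reached, passed the limit too. For the interaction 5 splits gave as many genes (2, highest other 361), so chance was not excluded. These splits exchanged genotypes within each operation, so a split can take in the genotype difference itself. The split with 361 genes was not tested further. Nor was chance excluded for the number of lists, where 61 splits gave as many in sham (2, highest other 15), 5 for TAC in wild type (14, highest other 16), 25 for TAC in G4D (11, highest other 16), 18 after TAC (9, highest other 13) and 59 for the interaction (4, highest other 13).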

How the results depend on the processing

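Median centring, the offset of 16 on the linear scale, the fit without 3 arrays in doubt and leaving out each array with the probe sets kept were tests chosen only after the result was seen. Across all alternatives but the last, 5224 of 5514 values of genes chosen for naming kept their direction and side of the threshold, 243 lost a call, 33 gained one, 1 reversed and 13 changed direction without a call either way. Of list values 3843 of 4124 did, 26 lost a call, 130 gained one, 3 reversed and 122 changed direction without a call. Offsets of 1 and 64 were not run, since the values are already log2, nor was a sex covariate, since the arrays did not split. The 40% of probe sets below the filter limit what dim genes can show. The cause was not tested for any change below unless a cause is named.

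With no filter the interaction had 1 called gene and the correlation of the TAC effects was 0.441. With the stricter filter, which tests fewer genes, sham had 15 and the interaction 20. In the values as deposited sham had 3 genes and 12 lists, TAC in wild type 95 genes, genotype after TAC 64 and the interaction 6. There Gata6 after TAC in G4D reversed to 0.039 and the sarcomere list after TAC in wild type to -0.21. The citric acid cycle list in the interaction reversed to 0.41. All genes shifted by 0.31, -0.096 and 0.42 in these comparisons, and relative to them the values were -0.27, -0.12 and -0.015. The shift does not account for the sarcomere list, which stayed below all genes there and after median centring. With median centring sham had 4 genes and 8 lists, TAC in wild type 388 genes, after TAC 185 and the interaction 10 genes and 7 lists, and the sarcomere list reversed to -0.15. With the mean of probe sets limma called 0 genes in the interaction (1064 at an unadjusted p under 0.05), against 2 with the brightest (1110). With trend and robust sham had 12 and the interaction 6. With array weights sham had 4 lists, genotype after TAC 829 genes and the interaction 24 genes and 9 lists. With the offset of 16 sham had 12 genes and the interaction 14. Without the 3 arrays in doubt genotype after TAC had 705 genes, the interaction 13 genes and 8 lists, and the dimmer Gata4 probe set stood at 0.053 in sham. With an estimated correlation camera called 0, 4, 3, 3 and 0 lists in sham, TAC in wild type, TAC in G4D, after TAC and the interaction.

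With the replicate block sham had 3 genes and 1 list, TAC in wild type 488 genes, genotype after TAC 274 and the interaction 1. Replicate numbers did not pair the samples, since 9 of 28 pairs of arrays with the same number had r over 0.1 (-0.36 to 0.42) and 2 of 21 arrays correlated best with their own number.

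Leaving out each array in turn gave 1 to 27 genes and 0 to 6 lists in sham, 564 to 1145 genes and 13 to 15 lists for TAC in wild type, 2405 to 3343 and 11 to 12 for TAC in G4D, 247 to 644 and 9 to 11 after TAC, and 1 to 29 and 2 to 6 for the interaction. The correlation ran from 0.685 to 0.734. These fits chose the probe sets again, so that Slc36a3 and Fgf6 fell below the filter without any of 7 arrays each, and Ppargc1a and Slc27a1 changed probe set without 4 and 2. With the probe sets kept, 3527 of 3654 values of genes chosen for naming kept their direction and side of the threshold, 117 lost a call, 7 gained one and 3 changed direction without a call. Slc36a3 and Fgf6 were called without each of the 21 arrays, and the interaction of Ppargc1a ran from -0.86 to -0.34. Gata4 ran from -0.31 to -0.19 in sham and from 0.09 to 0.24 after TAC on the brighter probe set, and from -0.34 to 0.053 and -0.068 to 0.30 on the dimmer one. Sham had 1 gene without wild-type sham sample 1 or 2 and 27 without G4D sham sample 2, 0 lists without G4D sham sample 5 and 6 without G4D sham sample 1. TAC in wild type had 564 without wild-type sham sample 1. Genotype after TAC had 247 without G4D TAC sample 1, and the interaction 29 without G4D TAC sample 4 and 2 lists without G4D sham sample 2.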

Other observations

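The tests of the MHC class II genes, the clock genes and the neighbours of Gata4 were chosen only after the result was seen. Some genes of MHC class II, which antigen-presenting cells use to show peptides to T cells, were lower in G4D than in wild type after TAC. They were not tested as a list. H2-Aa stood at -0.96 (adjusted p = 0.0153) and Cd74, which encodes the invariant chain, at -0.76 (adjusted p = 0.0341), beside H2-Ab1 at -0.91 (adjusted p = 0.0223). H2-Eb1 stood at -0.63 (adjusted p = 0.155) and was not called. H2-Aa, Cd74 and H2-Eb1 were chosen after their values were seen, and the call of Cd74 ended without any of 7 single arrays, wild-type TAC samples 2 to 6 and G4D TAC samples 2 and 4 (-0.78 to -0.59), and that of H2-Ab1 without wild-type TAC sample 2 (-0.81). The calls of H2-Aa, H2-Ab1 and Cd74 ended in the values as deposited, with the replicate block and with only the groups compared.

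Genes of the daily clock differed between groups. The mean of 9 genes that peak towards evening was higher in G4D sham than in wild-type sham by 0.68 and than in G4D TAC by 0.87, and the mean of 3 morning genes stood at -0.34 and -0.22 in the same comparisons (adjusted p = 0.0292 each by an exact permutation test, 6 comparisons, two-sided). The morning genes were tested in these comparisons alone, which share the G4D sham arrays. The adjustment does not cover this choice of genes and comparisons. Between wild-type TAC and wild-type sham the evening genes differed by 0.06 (exact permutation test, adjusted p = 0.824), and between G4D TAC and wild-type TAC by -0.24 (exact permutation test, adjusted p = 0.413). A different time of day of collection might give this, and then arrays high in evening genes should be low in morning genes within groups. Over 21 arrays the within-group Pearson r was -0.62 (permutation p = 0.0131), Spearman -0.34 (permutation p = 0.172), and r was -0.34 without the 2 arrays farthest from the median, so the relation rests on those arrays. The time of day and a difference between the groups themselves cannot be told apart, since no collection time is known here.

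A stretch of chromosome carried along with the targeted allele might change genes next to Gata4. Of the 100 tested genes nearest to it, 50 on each side, 3 (3.0%) were called for genotype averaged over both operations, against 2.63% of the other genes (Fisher's exact p = 0.748), so 3 genes were too few to decide.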
